A study of Rattus norvegicus with 31 samples.

How the data were processed

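RNA from rat peripheral blood mononuclear cells (PBMC, the lymphocytes and monocytes of blood) was measured on 31 Agilent 2-colour arrays, 1 array per sample. Per the labels, each array held 1 individual sample in red (Cy5) and the same reference pool in green (Cy3). The pool was made of equal parts of RNA from 5 randomly chosen samples per group, and no dye was swapped. A dye effect that is the same on all arrays therefore cancels between groups and does not in a single ratio. Samples were grouped by their titles into WT (7), CR (11) and CR-L (13). The titles say WT where the protocol speaks of controls, and these were taken as one group.

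The authors deposited 1 scanner file per array. Per the file headers, spot intensity and local background intensity were extracted with Agilent Feature Extraction, version 10.7.3.1 per the submitters' processing notes. Its log10 ratio of red over green is background-detrended and dye-normalized, per the file headers. A table of the whole series, with log2 values as the authors made them by steps not given in the sources used here, was also deposited. These tracked the log2 red intensity of the same array (lowest correlation 0.993 over probes) and not the log ratio (from -0.105 to 0.153). Every column of it had a median of 8.17, so each array had been set to a common median, and its further normalization stays unknown.

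From the scanner files, mean spot intensities were corrected with limma (version 3.58.1 in R 4.3.3) by normexp with an offset of 50 on the median local background. Loess within each array followed, with no normalization between arrays. Each array had 45018 spots, of which 1639 were control spots and were left out of the tests. Outlier spots were left out as well, 5483 over all arrays or 0.408% of values. Spots of one probe were averaged, which gave 41012 probes. Probes with red well above background on at least 7 of the 31 arrays were kept (26716). The probe with the highest mean intensity stood for each gene symbol, and probes without a symbol kept their own ID, which left 22258 features, with 0.033% of values missing. The array's names were updated through a reference table of the GRCr8 assembly, used for names alone. Of the probes, 18971 were named by accession, 218 by an accession in the description, 2996 by a current symbol and 204 by an older one. A further 1007 kept the file's name and 17616 had no symbol. Probe positions are those of the files, on the rat build rn4.

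Group means were compared with limma (lmFit and eBayes) over all 31 arrays, which share 1 estimate of the spread, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 differences of group means. The labels state no test. In all, 25 gene lists fixed before the data were examined were tested with limma's camera at its preset correlation of 0.01, and again with an estimated correlation. The lists cover blood cell types, leptin and insulin signalling, lipid handling, mitochondria, ribosomes, stress, inflammation, the cell cycle, the clock, hormones and chromatin. Fry and a permutation of the per-array list means were added after the data had been seen, as were called lists with each array left out and the genes taken from the other slides. That permutation was exact against WT and resampled between CR-L and CR.

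Named genes followed a rule set before the data were examined. It took the 10 largest changes per direction past the threshold among features with an established symbol. Directions with fewer were filled to 10 from those at an unadjusted p under 0.01, named as not past it. Added were up to 4 members with the smallest p of each list called by camera, at most 2 of every other list, and Lepr, Socs3, Cpt1a, Fasn, Srebf1, Slc27a2 and Insr where measured. Lepr was not among the features tested. Which of the list members allowed by the rule are named was settled after the values had been seen. That choice was first narrowed for length and then widened again, so that all genes the rule always names are in the text. Some genes that the rule takes are not reported here.

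The tests were checked on simulated data with 200 of 22258 features changed, in 5 runs. Each run held changes of 0.25, 0.5 and 1 together. For CR against WT, 37.6% of changes of 0.25 on the log2 scale were recovered, 88.4% of 0.5 and 98.5% of 1. For CR-L against CR the shares were 59.1%, 93.7% and 98.8%, and for CR-L against WT 43.6%, 88.7% and 97.6%. False calls averaged 4.4, 3.4 and 4.4 per run, and no feature was called where none was changed. For lists, 20 simulated data sets with no effect, analysed as CR against WT, gave a mean of 6.45 lists called by camera at its preset correlation, and up to 13. With an estimated correlation the mean was 0.05.

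Median red intensity per array lay between 69.8 and 235, against a median local background near 29, and 57.5% to 83.6% of red spots were well above background. The number of arrays limits the precision. The arrays lay on 8 slides, each with a scan time of its own. Slides 1 to 7 held 1 WT array each with CR and CR-L arrays, and slide 8 held none. Alternatives covered the background correction, the software's own log ratios, between-array normalization, the red channel alone, the series table, the filter on dim probes and single probes. They also covered slide, position and replicate number as blocks, array weights, a trended fit, Y-linked transcripts and cell type lists as covariates, fewer groups, the threshold and each array left out. Other tools were statmod 1.5.0, Python 3.11.15 and plotting with matplotlib 3.10.9.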

Results

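The series asked whether leptin given to suckling pups offsets what caloric restriction of their dams during pregnancy leaves in the adult offspring, and its title states that it does. Of 16 mated rats, some dams were fed 20% less from day 1 to day 12 of pregnancy. Their offspring were suckled without supplement (CR) or received leptin, a hormone of fat tissue also present in milk, until postnatal day 21 (CR-L). The daily dose rose from 1.0 to 43.8 ng, 5 times the intake from milk. Offspring of unrestricted dams are called WT. After 4 months on chow, PBMC were taken and expression was measured in 7 WT, 11 CR and 13 CR-L samples. With 31 samples from at most 16 litters, some animals share a dam. The labels name neither litter nor sex per sample, so p-values across samples could be too small. All values are log2 ratios of a sample over the reference pool, with ± SE for a difference between groups.

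Blood cells of CR offspring differed from WT in 104 of 22258 features, 79 higher and 25 lower. The largest decrease among named genes past the threshold was that of Traf6, an adaptor that passes Toll-like and interleukin-1 receptor signals to NF-kB, which was 1.52-fold lower (-0.60 ± 0.14, adjusted p = 0.0492). Foxo1, a transcription factor restrained by insulin signalling (probe on chromosome 2, 141201740 to 141201799, rn4), fell from 0.40 ± 0.26 (SD, n = 7) in WT to -0.058 ± 0.22 (SD, n = 11) in CR (-0.46 ± 0.096, adjusted p = 0.0245). The kinase gene Map3k9 was lower as well (-0.47 ± 0.10), as were the histone H3 genes H3f3b (-0.42 ± 0.096) and Hist2h3c2 (-0.34 ± 0.081). Zbtb43, Cdadc1, Oser1, Edc3 and Ankrd49 lay between -0.37 and -0.31. Among the higher genes past the threshold, Rnf187 (0.52 ± 0.12), Mat2a, which makes the methyl donor S-adenosylmethionine (0.50 ± 0.12), and Hspa4, a chaperone of the Hsp110 family (0.50 ± 0.10, adjusted p = 0.0172), changed most. The chromatin remodeller Chd1 rose by 0.45 ± 0.073 (adjusted p = 0.00333). Zfp260, Pdf, Rbm12, Prep, Zfp467 and Tmpo were higher by 0.36 to 0.40. Another probe of Hspa4, Edc3 and Hist2h3c2, and 1 of 2 other probes of Chd1, went the opposite way.

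The count against WT depended on single arrays, from 17 genes without WT replicate 4 to 207 without CR replicate 9, and was 0 with the authors' series table. With the red channel alone it was 34, of which 14 were higher and 20 lower. With slide as a block it was 70. For the 100 genes with the smallest p in the arrays of the other slides, the median change from WT to CR in that direction was 0.0545 to 0.388 within the slide left out, over 7 slides.

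**Figure D1:**
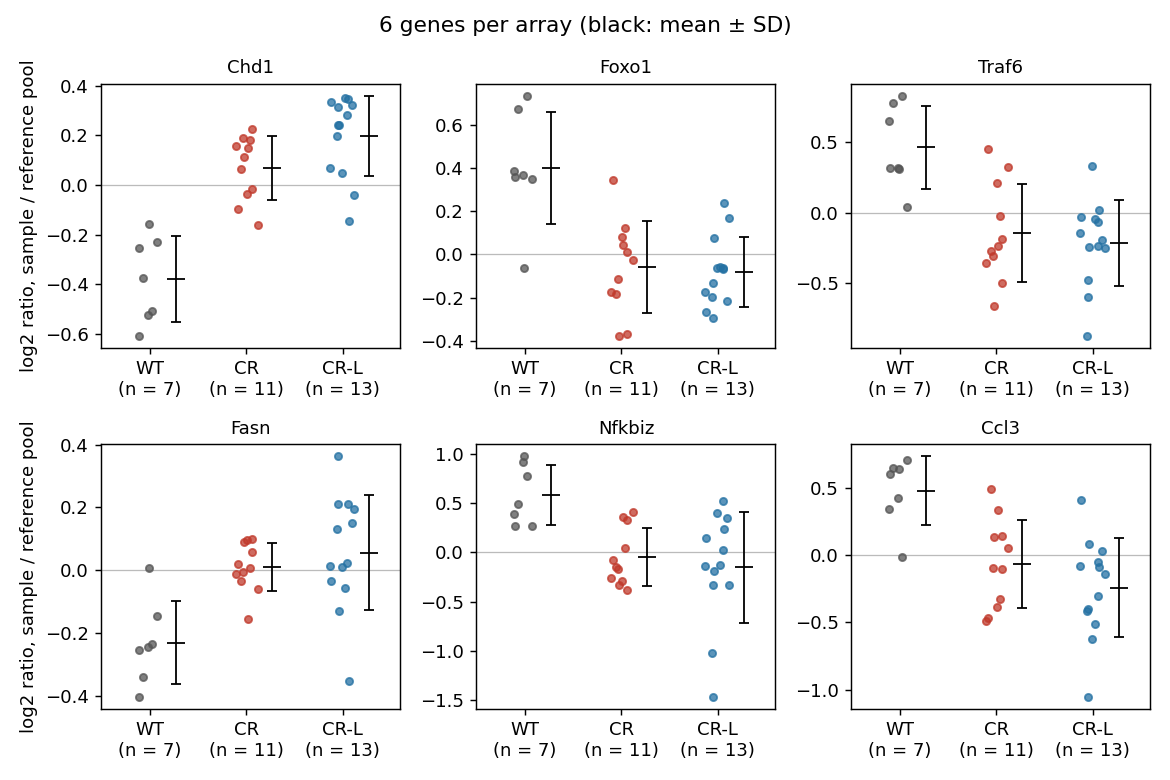
Log2 ratio of sample over reference pool for Chd1, Foxo1, Traf6, Fasn, Nfkbiz and Ccl3, one point per array, with black marks for mean and SD in WT (n = 7), CR (n = 11) and CR-L (n = 13). For Chd1 the WT arrays lie from -0.61 to -0.16 and the CR-L arrays from -0.15 to 0.35, and for Foxo1 the 2 restricted groups have means of -0.058 and -0.081 against 0.40 in WT.

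Of the 25 gene lists, 10 differed between CR and WT by camera at its preset correlation, 3 higher and 7 lower. None held with an estimated correlation (adjusted p = 0.671 for each of the 10), and fry and the permutation of list means called 0. Heat shock proteins were higher (16 of 18 members above 0, camera adjusted p = 2.83e-06). This list as fixed also holds genes of the endoplasmic reticulum and its stress response (Hspa5, Hsp90b1, Pdia4, Pdia6, Calr and Ddit3). It is therefore not a list of cytosolic heat shock proteins alone. Only Hspa4 passed over all genes, and 8 members passed when adjusted over the list alone, Pdia4 among them (0.34 ± 0.087). Inflammatory cytokines and NF-kB genes were lower (18 of 27 below 0, adjusted p = 0.00128). No member passed over all genes, and 5 lower and 1 higher did so adjusted over the list alone, including the adhesion molecule Icam1 (-0.51 ± 0.13), the chemokine Ccl3 (-0.55 ± 0.15) and Nfkbiz (-0.63 ± 0.20). Immediate early genes were lower (23 of 27, adjusted p = 0.000431), with Gadd45b at -0.64 ± 0.21 and Ppp1r15a at -0.22 ± 0.11, neither past the threshold. Cytosolic ribosomal proteins were lower by a small amount (65 of 77, median -0.050, adjusted p = 4.87e-07). Rpl21 stood at -0.24 ± 0.062, the 1 member past the threshold adjusted over the list alone (1 of 6 other probes went the opposite way), and Rpl10 at -0.17 ± 0.051. The ribosomal list mean was 0.429 in WT replicate 1 and 0.121 to 0.195 in the other WT arrays, and without that array its difference went from -0.0486 to -0.00906 (camera adjusted p = 0.0565).

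Markers of blood cell types differed between CR and WT by the same test. T cell genes were higher (adjusted p = 0.0138), with Trat1 at 0.25 ± 0.076 and Cd5 at 0.28 ± 0.091, both past the threshold when adjusted over the list alone. Genes of platelets were also higher (16 of 16 members, adjusted p = 0.0201), with Vwf at 0.45 ± 0.33 and Itgb3 at 0.25 ± 0.19. B cell genes (adjusted p = 0.0134; Vpreb3 -0.36 ± 0.17, Ly86 -0.27 ± 0.13) and monocyte genes (adjusted p = 0.0134; Fcgr1a -0.27 ± 0.16, Cybb -0.21 ± 0.13) were lower. So were granulocyte genes (adjusted p = 0.0134; Hp -0.31 ± 0.12, Il1r2 -0.47 ± 0.29) and interferon response genes (adjusted p = 0.0138; Oasl -0.27 ± 0.096, Dhx58 -0.28 ± 0.11). No member of these 6 lists passed over all genes. Without WT replicate 7, whose platelet mean was -1.401, none of the 6 was called and 4 lists in all were. The differences then went from 0.389 to 0.22 for platelets (adjusted p = 0.353), 0.0937 to 0.06 for T cells (0.247), -0.103 to -0.0597 for monocytes (0.247) and -0.0892 to -0.0515 for interferon response (0.247), with B cells and granulocytes at 0.135 each. Calls also ended, by adjusted p, for B cells without CR replicates 4 (0.0682) and 6 (0.125, -0.143 to -0.0715), T cells without CR replicate 1 (0.062), and granulocytes without WT replicate 3 (0.128, -0.195 to -0.106) and CR replicate 3 (0.0605). They ended for monocytes without WT replicate 6 (0.0884) and CR replicate 3 (0.0786, to -0.0674), platelets without WT replicate 1 (0.0555) and CR replicates 2 (0.0647) and 3 (0.0786), and interferon response without WT replicates 3 (0.0665) and 6 (0.0969) and CR replicates 1 (0.062) and 5 (0.0716). The B cell difference grew to -0.228 without WT replicate 1.

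The other 15 lists had camera adjusted p from 0.0586 (antigen presentation) to 0.928. Of leptin signalling, Foxo1 passed over all genes and Irs2, an insulin receptor substrate (-0.44 ± 0.15), only adjusted over the list alone. Fasn, the fatty acid synthase, stood at 0.24 ± 0.068 (adjusted p = 0.0954) and passed adjusted over its list alone, as did 1 member each of fatty acid oxidation and cholesterol synthesis and handling, 1 of glucocorticoid response and 2 of the circadian clock. No member of the lists for insulin signalling and glucose uptake, oxidative phosphorylation, NK and cytotoxic cells, erythroid cells, antigen presentation, antioxidant defence, proliferation, DNA methylation and chromatin modifiers, or thyroid hormone and sympathetic receptors passed either way. Socs3 (-0.098 ± 0.18), Cpt1a (0.11 ± 0.11), Insr (0.024 ± 0.077), Srebf1 (-0.0028 ± 0.072) and Slc27a2 (0.35 ± 0.85) did not pass, and the sign of Insr turned in 3 alternatives and that of Srebf1 in 1. A single low WT array raised the differences of Cpt1a (replicate 5 at -0.627, others -0.106 to 0.18) and Insr (replicate 6 at -0.511, others 0.00879 to 0.208).

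Offspring that had received leptin differed from WT in 789 features, 478 higher and 311 lower. The named genes with the largest decreases past the threshold belong in part to the NF-kB system. Whether more of them do than among all features was not tested. Nfkbiz (-0.73 ± 0.19, adjusted p = 0.0259), Ccl3 (-0.72 ± 0.15, adjusted p = 0.00466), Birc3 (-0.66 ± 0.15) and Traf6 (-0.68 ± 0.14) were lower, and so were Tnfaip3 (-0.71 ± 0.18) and Nfkbia (-0.64 ± 0.17), which encode inhibitors of NF-kB. Nfkbiz was lowest in CR-L replicates 2 (-1.021) and 6 (-1.463), with the other CR-L arrays from -0.3341 to 0.5174. The lymphocyte activation marker Cd69 (-0.61 ± 0.18), Ldaf1, Zbtb10 and Irs2 (-0.56 ± 0.14, adjusted p = 0.0214) completed the 10. Among named genes past the threshold Tmem204 rose most (0.83 ± 0.18, 1.78-fold, adjusted p = 0.00732), followed by the co-chaperone Dnaja1 (0.67 ± 0.19), Chd1 (0.58 ± 0.071, adjusted p = 3.18e-05) and Cxcr3, a chemokine receptor of activated T cells (0.54 ± 0.11). Hyal2, Tmem33, Cptp, Ccnd1 and Zfp260 were higher by 0.48 to 0.53. Of 2 other probes of Chd1, 1 went the opposite way.

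Leaving out an array gave 420 (without WT replicate 4) to 1100 genes (without CR-L replicate 10). Slide as a block gave 833, and the 100 genes with the smallest p in the other slides had a median change in that direction of 0.164 to 0.469 within the slide left out. With 4 cell lineage lists as covariates 219 genes passed, while the median change of the 789 genes went from 0.266 to 0.245 and their median SE from 0.0642 to 0.0725.

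In CR-L against WT, 5 lists differed by camera. Heat shock proteins were higher (adjusted p = 1.24e-05, or 0.647 with an estimated correlation). Of their 18 measured members, 4 passed over all genes and 10 adjusted over the list alone, with Dnajb1 at 0.43 ± 0.11, Pdia4 at 0.39 ± 0.084 and Hspa4 at 0.40 ± 0.097, whose other probe went the opposite way. The list mean rose from -0.22 ± 0.14 (SD, n = 7) in WT to 0.039 ± 0.13 (SD, n = 13), exact permutation p = 0.000529, adjusted p = 0.0132. Within the 7 slides, heat shock means averaged over CR and CR-L arrays lay 0.064 to 0.52 above the WT array. This range does not describe CR-L alone. On slide 1 (0.064), CR-L replicates 1 and 2 stood at 0.334 and -0.162, against 0.078 in WT replicate 1. On slide 3 (0.52), CR replicates 3 and 4 stood at 0.538 and 0.01 and CR-L replicate 5 at 0.03, against -0.329 in WT replicate 3. Ribosomal proteins were lower (68 of 77 below 0, adjusted p = 4.75e-13, or 0.646 with an estimated correlation), and Rpl21 (-0.23 ± 0.060), Rps9 (-0.15 ± 0.040) and Rpl12 (-0.18 ± 0.052) passed over all genes, 6 adjusted over the list alone. Of 6 other Rpl21 probes, 2 went the opposite way. Without WT replicate 1 (list mean 0.429, others 0.121 to 0.195) the ribosomal difference went from -0.093 to -0.0535 (camera adjusted p = 4.03e-05). Fry called these 2 lists (adjusted p = 0.0440 for each). Inflammatory cytokines and NF-kB genes were lower (adjusted p = 0.00400, or 0.659 with an estimated correlation), with 7 members lower, among them Icam1 (-0.54 ± 0.13) and Bcl3 (-0.49 ± 0.13), and 1 higher, over all genes and over the list alone. The inflammatory list mean was lowest in CR-L replicates 2 (-0.522) and 6 (-0.73). The other CR-L arrays lay from -0.226 to 0.305, against a WT mean of 0.131 (exact permutation p = 0.132). Immediate early genes (adjusted p = 0.00400; Cd69 the 1 member past the threshold; Klf6 -0.27 ± 0.093) and B cell genes (adjusted p = 0.00400; Fcer2 -0.50 ± 0.19, Ly86 -0.29 ± 0.12; no member past it) were lower, both with adjusted p = 0.659 with an estimated correlation. Without CR-L replicate 6 the immediate early list was not called (adjusted p = 0.0547).

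**Figure D2:**
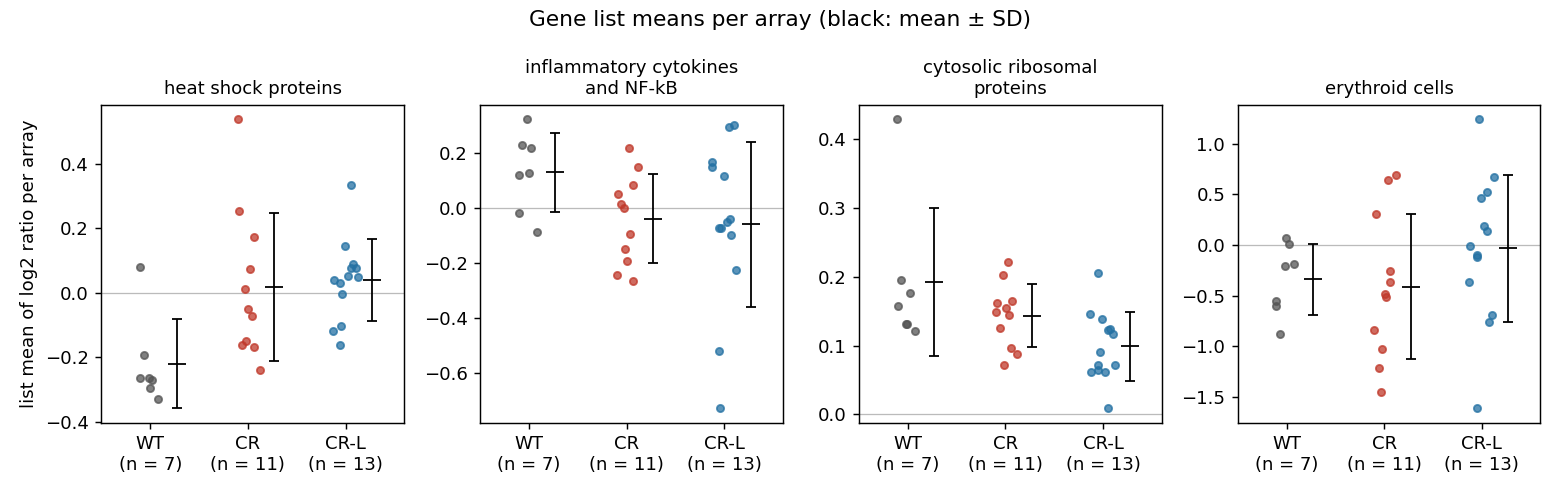
Mean log2 ratio over the measured members of 4 gene lists, one point per array, with black marks for mean and SD in WT (n = 7), CR (n = 11) and CR-L (n = 13). Heat shock means lie at -0.22 in WT, 0.018 in CR and 0.039 in CR-L, with 1 WT array at 0.078, and erythroid means spread from -1.61 to 1.24 within CR-L.

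The other 20 lists had camera adjusted p from 0.0971 (fatty acid oxidation) to 0.954, though single metabolic genes passed over all genes. Fasn (0.29 ± 0.066, adjusted p = 0.0111), the fatty acid oxidation genes Cpt2 (0.24 ± 0.065) and Hadha (0.18 ± 0.045), and Insig2 (0.22 ± 0.063) and Nsdhl (0.21 ± 0.061) of cholesterol synthesis and handling were higher. Foxo1 (-0.48 ± 0.093, adjusted p = 0.00301) and the cytochrome oxidase subunit gene Cox7c (-0.44 ± 0.088) were lower. The replication gene Mcm6 (-0.29 ± 0.061) and the clock gene Nr1d2 (-0.28 ± 0.060) were lower, and Fkbp5, a glucocorticoid target (0.32 ± 0.085), was higher. Another probe of Hadha, Insig2 and Cox7c went the opposite way. Adjusted over the list alone, 2 genes passed for fatty acid oxidation, 1 for insulin signalling and 1 for oxidative phosphorylation. By the same adjustment cholesterol synthesis and handling had 5 higher and 2 lower genes, lipogenesis and lipid uptake 2 and 1, leptin signalling 1 and 2, the circadian clock 2 and 2, glucocorticoid response 1 and 2, and proliferation 1 and 1. T cells and thyroid hormone and sympathetic receptors had 2 higher genes each. Of the markers of other cells, erythroid genes had a median of 0.26 (22 of 23 above 0, adjusted p = 0.113) and platelet genes 0.046 (adjusted p = 0.885). Socs3 (-0.099 ± 0.18), Cpt1a (0.048 ± 0.10), Insr (-0.023 ± 0.074), Srebf1 (0.013 ± 0.070) and Slc27a2 (-1.01 ± 0.83) did not pass, and the sign of Insr and of Srebf1 turned in 2 alternatives each. Here too, the low values of WT replicate 5 for Cpt1a (-0.627) and WT replicate 6 for Insr (-0.511) raised the differences.

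No feature differed between CR-L and CR by limma (smallest adjusted p = 0.9998), and 516 of 22258 (2.32%) had an unadjusted p under 0.05. All alternatives also gave 0 genes. In simulated data 93.7% of changes of 0.5 on the log2 scale were recovered in this comparison and 59.1% of 0.25, so smaller differences were not well detectable. These runs mixed changes of 0.25, 0.5 and 1, and the larger ones ease the adjusted threshold for the smaller. Recovery of changes of 0.25 alone was not simulated and could be lower. The genes with the smallest p, none past the threshold, were Gnal (0.13 ± 0.037), Kcnab2 (0.27 ± 0.078), Tlr1 (0.25 ± 0.083), Or5aq6, Nrros, Csf2rb, Apobr, Reg3a, Thrb and Zfp483 above 0, and Chrnb4 (-0.18 ± 0.050), Smarcad1, Ccdc117, Slc45a4 and C1qbp below 0. Or5aq6, Csf2rb, Reg3a, Chrnb4 and Slc45a4 were well above background on only part of the arrays, and another probe of Kcnab2, Apobr and Smarcad1 went the opposite way. Socs3, which restrains leptin receptor signalling (-0.0017 ± 0.15), Cpt1a (-0.060 ± 0.089), Fasn (0.047 ± 0.058), Srebf1 (0.016 ± 0.061) and Insr (-0.047 ± 0.065) did not pass, and the sign of Socs3 turned in 4 alternatives. Slc27a2, a fatty acid transporter, stood at -1.36 ± 0.72.

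Camera called 5 lists between CR-L and CR, and none held with an estimated correlation. Erythroid genes were higher (19 of 23, median 0.42, adjusted p = 9.61e-07, or 0.915 with an estimated correlation), with the red cell transcription factor Klf1 at 0.62 ± 0.27, Hemgn at 0.62 ± 0.29 and the globin Hbe1 at -0.51 ± 0.25. Platelet genes were lower (16 of 16, median -0.37, adjusted p = 0.000275, or 0.991 with an estimated correlation), with Ppbp at -0.59 ± 0.38 and Gp1bb at -0.60 ± 0.44. Ribosomal proteins were lower (adjusted p = 1.45e-05; Rpl17 -0.11 ± 0.041, Rpl27 -0.11 ± 0.043). Genes of cholesterol synthesis and handling (adjusted p = 0.0181; Nr1h3 0.23 ± 0.13, Nsdhl 0.074 ± 0.054) and of proliferation (adjusted p = 0.0187; Ube2c 0.45 ± 0.19, Ccnb2 0.12 ± 0.049, well above background on only part of the arrays) were higher, these 3 lists each with adjusted p = 0.915 with an estimated correlation. Platelet means were lowest in CR-L replicates 3 (-2.695) and 7 (-2.285), and the difference of -0.355 went to -0.16 without the first (adjusted p = 0.14) and -0.194 without the second (0.0908). The cholesterol list was not called without CR replicates 3 (0.0571) or 11 (0.0613) or CR-L replicates 3 (0.121), 7 (0.0963) or 11 (0.0588), nor proliferation without CR replicates 1 (0.109) or 3 (0.0571) or CR-L replicate 9 (0.0986). No member of any list passed, over all genes or over the list alone. The other 20 lists had adjusted p from 0.0822 (monocytes) to 0.995, with inflammatory genes at 0.960 (Tnfaip3 -0.35 ± 0.16) and heat shock proteins at 0.914. Median, mean and camera direction had the same sign for every list in each comparison that called it. Among lists not called they differed for oxidative phosphorylation in all 3 comparisons, for leptin signalling, lipogenesis and lipid uptake, antioxidant defence and proliferation in CR against WT, or for the circadian clock and glucocorticoid response in CR-L against CR.

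CR and CR-L differed from WT in overlapping genes. Of the 104 genes called in CR, 103 were also called in CR-L, 78 higher and 25 lower in both. Independent lists would share 1.70 and 0.349, but these 2 comparisons share the WT arrays. With the WT arrays split between the comparisons, no gene was shared, but the median number of calls was also 0 for each, so that split says nothing about overlap. Across genes, which are not independent replicates, the fold changes correlated at r = 0.80, within the range of 0.21 to 0.89 (mean 0.62) of groups with no effect, and at 0.38 on average with WT split (0.12 to 0.56). Their covariance of 0.0122 also lay within the range with no effect (0.00179 to 0.0158).

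**Figure D3:**
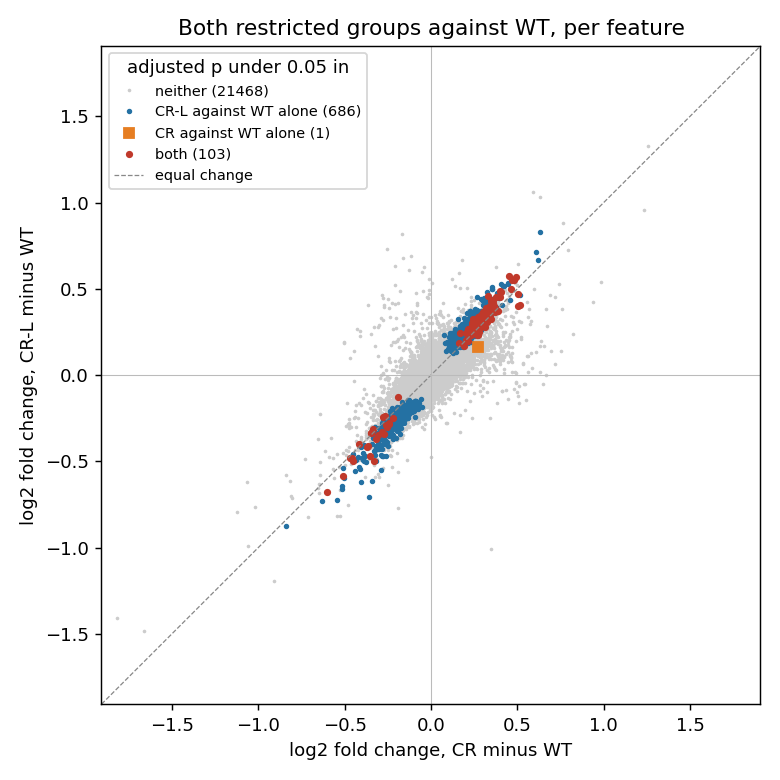
Log2 fold change of CR minus WT (horizontal axis) against CR-L minus WT (vertical axis) for 22258 features, coloured by adjusted p under 0.05 in CR alone (1), CR-L alone (686) or both (103). The dashed line marks equal change, and the 103 shared features lie along it on the same side of 0. Passing in CR-L alone is not a difference between CR-L and CR, where no feature passed.

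Whether leptin moved expression back toward WT was examined from the opposition of CR-L minus CR to CR minus WT. The correlation across genes was -0.26. Because both share the CR arrays, groups with no effect gave -0.44 on average (SD 0.17), and covariance was -0.00251 against -0.00376 (-0.0109 to 0.000659). With the CR arrays split, the mean correlation was 0.055 (-0.22 to 0.37). Of the 104 genes changed in CR, the CR-L mean lay on the WT side of the CR mean for 26 (25%), and on the same side of WT as CR for all 104. Those genes were chosen for the distance between CR and WT, and CR-L was set against the same WT arrays. The side of WT was therefore close to fixed in advance. Splits of the CR arrays put 16.2% on the WT side (0% to 64%). The WT arrays were not split here, and no share was simulated for groups without a leptin effect. In 45 of the 100 splits fewer than 10 genes passed, and the 100 with the smallest p were used.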

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

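The tests of list counts, of both restricted groups together against WT, of cell makeup, of sex, of the single WT array behind the heat shock score, and of red cells and platelets were settled after related results had been seen. WT was the one group of a size (7 arrays) in which single arrays standing apart were looked for. Of 131 measures, 16 had an array separated from the other 6 by a large part of the group's range, where chance gives about 6.55. WT replicate 1 accounts for 10 of these. The SD of log2 ratios over probes was low on this array (0.1227), on CR replicate 11 (0.1139) and on CR-L replicate 12 (0.0885). On the other arrays it was 0.1657 to 0.295, and the cause was not tested. The list means of WT replicate 1 were -0.464 for B cells (others 0.0129 to 0.271), 0.282 for NK and cytotoxic cells (others -0.206 to -0.0821), 0.429 for ribosomal proteins (others 0.121 to 0.195) and 0.0777 for heat shock proteins (others -0.329 to -0.193). Its log2 ratios were 0.125 for Map3k9, -0.383 for Ly86, 0.037 for Dnaja1 (others -0.913 to -0.724), -0.675 for Fcer2, 0.503 for Rpl12 and 0.255 for Fkbp5. WT replicate 6 was the brightest array of its group, with a median red intensity of 235 (others 77.0 to 88.8), 83.6% of red and 71.4% of green spots well above background, and log2 ratios of -0.511 for Insr and -0.423 for Zfp483. In WT replicate 5, Cpt1a stood at -0.627 (others -0.106 to 0.18).

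The first pattern is the difference of both restricted groups from WT, in which 103 of the 104 genes called in CR were among the 789 called in CR-L. For the gene counts against WT, the tables argue against a chance split of single arrays. Of 100 splits, only 1, the real one, reached 104 genes in CR (highest other 1), 789 in CR-L (highest other 227) and 817 for both restricted groups together (highest other 6). These splits treat the arrays as independent, so chance differences between litters were not tested. The next tests are of the difference itself, not the sharing. Leaving out 1 WT array kept 0.968 of the median change of the CR-L genes at worst (0.257 of 0.266, without WT replicate 4). These genes were called with all the WT arrays, so their median could hardly fall, and this cannot decide on a single array. Calls fell to 17 in CR and 420 in CR-L without WT replicate 4. For the 100 genes with the smallest p in the other slides, the median change against the left-out WT array kept its direction. It was 0.0545 to 0.388 in CR and 0.164 to 0.469 in CR-L, which argues against a single WT array for those genes. The tables argue against slides, with 1.02 kept (0.271). With 6 cell lineage lists as covariates 0.939 was kept (0.25), while the calls in CR-L fell from 789 to 307 as the median SE rose from 0.0642 to 0.071, and those in CR rose from 104 to 156 (median change 0.306 to 0.291). A mix of males and females would leave a gap in Y-linked transcripts, and Ddx3y and Eif2s3y were well above background on 31 of 31 arrays with a largest gap of 0.305 between neighbouring values, which argues against it if their probes read the Y-linked genes alone. The 2 genes correlated at only 0.0815 over the arrays. With their mean as a covariate, calls fell from 789 to 408 in CR-L and from 104 to 57 in CR. The study's biological explanation, restriction of the dam, may account for the pattern as a hypothesis, but shared litters stay open, since no label gives them per sample.

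The second pattern is a higher heat shock list together with a lower inflammatory list in both restricted groups by camera, where neither list held with an estimated correlation (adjusted p of 0.671 in CR for both, and in CR-L 0.647 for heat shock and 0.659 for inflammatory genes), and by permutation of list means only heat shock in CR-L did (adjusted p = 0.0132, against 0.163 for both lists in CR and 0.33 for inflammatory genes in CR-L). The per-array difference between these list means was -0.352 ± 0.185 (SD, n = 7) in WT and 0.079 ± 0.261 (SD, n = 24) in restricted arrays, a difference of 0.431 (exact permutation p = 0.000287, chosen after the lists had been seen), with 23 of 24 restricted arrays above the WT mean. The tables argue against a single WT array (0.908 kept without WT replicate 6) and against loess or the reference channel (0.983 kept in the red channel alone). The red channel values keep the same background correction, so that step was not tested for this score. Within the 7 slides the difference was 0.20 to 0.694. With 6 cell lineage lists as covariates 0.665 was kept (0.286 ± 0.0897, SE), so blood cell makeup may account for part of it and cannot be told apart from a change within cells. Handling of blood before freezing was not tested, and the restricted diet of the dam stays open beside it.

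The third pattern is the higher erythroid and lower platelet lists in CR-L against CR. Per-array list means overlapped widely, with erythroid means of -0.0316 ± 0.726 (SD, n = 13) in CR-L and -0.41 ± 0.718 (SD, n = 11) in CR (permutation p = 0.213), and platelet means of -0.354 ± 1.09 and 0.00127 ± 0.39 (permutation p = 0.334). These values are consistent with chance differences in the red cells and platelets carried into each sample, and a leptin effect on these cells was not tested apart from that. Counts of lists called by camera could not be set apart from chance in any comparison. As many lists were called in 12 of 100 splits for CR against WT (real 10, highest other 13), in 75 for CR-L against CR (real 5, highest other 12) and in 79 for CR-L against WT (real 5, highest other 14). For genes in CR-L against CR, all 100 splits reached the real count of 0 (highest other 2).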

How the results depend on the processing

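The 2 settings that leave out named arrays for brightness or low spread, fry, the permutation of list means and the settings for where CR-L lies were added after the data had been seen. CR-L against CR gave 0 genes in every alternative. Genes in CR against WT numbered 65 with the software's log ratios, 34 with the red channel alone, 0 with the series table (2135 at an unadjusted p under 0.05), 66 with no filter on dim probes, 170 with probes above background on all 31 arrays, 397 with array weights, 57 with Y-linked transcripts as a covariate, 68 with 4 lineage lists as covariates, 197 with only the 2 groups compared and 339 at adjusted p under 0.1. Those in CR-L against WT numbered 500 with the series table, 408 with Y-linked transcripts, 219 with 4 lineage lists and 1348 at adjusted p under 0.1. With Y-linked transcripts the median change of the called genes was 0.295 (from 0.306) in CR and 0.24 (from 0.266) in CR-L, and with 4 lineage lists 0.292 and 0.245. Without WT replicate 6 the counts were 27 and 525, and without WT replicate 1, CR replicate 11 and CR-L replicate 12 together 66 for CR and 8 lists for CR-L against WT. The cause of these moves was not tested, apart from the threshold and the numbers of features, arrays and groups.

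Lists for CR-L against CR numbered 3 with the software's log ratios, 2 with the red channel, 3 with no filter and 3 with slide as a fixed block. Lists for CR-L against WT numbered 9 with no filter, 3 with Y-linked transcripts and 3 with 4 lineage lists. Lists for CR against WT numbered 6 with array weights, 5 with Y-linked transcripts and 3 with 4 lineage lists. With an estimated correlation all 3 comparisons gave 0 lists, fry gave 0, 0 and 2 and the permutation 0, 0 and 1. The share of higher genes in CR, 76% in the main setting, was 65.2% without background correction, 58.5% with the software's log ratios and 41.2% with the red channel alone. Normalization between arrays by Aquantile leaves log ratios as they are and so tests nothing. The opposition of the leptin to the restriction difference moved from -0.26 to -0.059 with 4 lineage lists. The share of CR genes with CR-L on the WT side, 25% in the main setting, was run in 3 alternatives only, and was 18.8% without background correction, 26.2% with the software's log ratios and 20% with slide as a block.

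With replicate number as a block, CR against WT gave 241 genes and CR-L against WT 9 lists. The numbers do not pair the samples: 25 pairs with equal numbers had a mean correlation of 0.0338 (-0.425 to 0.445), and 3 of 31 arrays correlated best with their own number.

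Leaving out each array gave 17 to 207 genes and 4 to 11 lists for CR against WT, 0 genes and 3 to 7 lists for CR-L against CR, and 420 to 1100 genes and 4 to 8 lists for CR-L against WT. CR against WT fell to 27 without WT replicate 2, 17 without 4, 47 without 5 and 27 without 6. It fell to 40 without CR replicate 3, 33 without 4, 65 without 5, 47 without 6, 64 without 7 and 28 without 8. It rose to 158 without CR replicate 1, 207 without 9, and to 193 and 187 without CR-L replicates 5 and 10. CR-L against WT fell to 447, 420, 461 and 525 without WT replicates 2, 4, 5 and 6.

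Named genes were followed only without background correction, with the software's log ratios, the series table, both changes of the filter, both slide blocks and the replicate block. In these settings 5 results near 0 changed sign, none past the threshold. Insr in CR against WT became -0.0153 without background correction, -0.0357 with the software's log ratios and -0.0601 with the series table. Insr in CR-L against WT became 0.00056 with slide as a block and 0.0309 with the replicate block. Socs3 in CR-L against CR became 0.0167, 0.0216 and 0.0424 in the first 3 of these settings and 0.0506 with the replicate block. Srebf1 became -0.00391 and -0.00448 in CR-L against WT without background correction and with the software's log ratios, and 0.00269 in CR against WT with the series table. Of 127 results of genes the naming rule takes, 6 lost the threshold without background correction, 14 with the software's log ratios, 11 with no filter, 11 with slide as a block and 7 with the replicate block, and 30 of 124 did with the series table, among them all 20 of CR against WT. The number of arrays and dim probes limit what can be called.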

Other observations

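The tests by fry for changes in either direction and the search for separated values were chosen after the data had been seen. In CR-L against WT, genes of cholesterol synthesis and handling changed in either direction by fry (adjusted p = 0.00216), with 20 of 27 above 0 and 7 below. Proliferation genes did so as well (adjusted p = 0.00908, 22 of 30 above 0), as did the inflammatory list (0.00216), ribosomal proteins (0.00448) and heat shock proteins (0.0173). This test does not set a list against the other genes, and 16.62% of all features had an unadjusted p under 0.05 here. It therefore cannot tell these lists from ordinary ones. For cholesterol and proliferation, camera (adjusted p = 0.1095 and 0.2237) and fry for 1 direction (0.178 and 0.255) made no call.

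For 12 features the log2 ratios of the 31 arrays fell into separate ranges at least 0.75 apart, with at least 3 arrays in each and a gap over 3 times the SD within them, a rule set after the values of Slc27a2 had been seen. Rpl13 lay between -2.9 and -2.25 on 7 arrays (2 WT, 1 CR, 4 CR-L) and between 0.186 and 0.72 on 24, and its other probe had no such gap. RT1-Ba, a class II histocompatibility gene, lay between 1.27 and 1.93 on 5 arrays (2 WT, 2 CR, 1 CR-L) and between -2.27 and -0.267 on 26. Ldhb, a lactate dehydrogenase subunit gene, lay between -2.79 and -1.73 on 13 arrays (5 WT, 4 CR, 4 CR-L) and between -0.617 and 0.986 on 18. Slc27a2 did not meet the last part of the rule (a gap of 1.59 times the SD), with values of -4.03 to -3.23 on 9 arrays (1 WT, 2 CR, 6 CR-L) and -1.95 to 1.82 on 22. No explanation of these ranges was tested. The Y-linked genes Ddx3y (-0.419 to 0.49) and Eif2s3y (-0.451 to 0.335) were well above background on 31 of 31 arrays and had no such gap.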
